A study of Mus musculus with 6 samples.

How the data were processed

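RNA from mouse eosinophils grown out of bone marrow was sequenced in 6 libraries, 3 from cells exposed to the cytokine IL-33 at 2.5 ng/mL for 3 hours and 3 from cells given the vehicle, phosphate-buffered saline (PBS). Per the labels' protocols, wild-type marrow was expanded with stem cell factor and FLT3 ligand and then matured in IL-5 at 20 ng/mL. The cells were used on day 14, after dead cells had been removed. Total RNA was depleted of ribosomal RNA and made into libraries with a directional kit, which keeps the strand of each transcript. The labels do not say whether libraries of a group came from separate mice or cultures, so p-values measure only the spread between these libraries, which may be technical.

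The authors deposited one table of normalized gene counts, a signal in which each library's gene counts had been divided by one factor. Per the submitters' processing notes, HISAT2, HTSeq and DESeq2 were used with genome build mm10. Tool versions, the gene annotation and the strand setting of the counting are not given in the sources used here. Each library's values were whole multiples of its smallest value, so reads could be recovered: 100% of values came out whole within 0.1 of a read. The recovered reads gave each library's depth and served for count-based alternatives. The table lists genes by symbol. Of its 23420 genes, 22994 were matched to 1 gene of the GENCODE vM21 annotation of GRCm38 (mm10), 1257 of them through an older symbol. Coordinates are the 1-based spans of those annotated genes. Several symbols in the table are older names, such as Siglec5 for Siglecf, Emr1 for Adgre1, Gpr44 for Ptgdr2 and Ero1l for Ero1a.

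Depth was limited by Rn45s, the gene of the ribosomal RNA precursor, which took between 13.7% and 59.6% of the recovered reads of a library. Whether these reads came from the precursor or from mature ribosomal RNA left after depletion was not tested. Between 4229504 and 7129435 reads remained for other genes. Sequenced reads without molecular identifiers are not independent molecules, so counting intervals cover counting error only. Because the strand setting of the counting is not given, reads of overlapping genes, antisense ones included, may not be told apart. Genes with near-identical copies, such as Ear1, Ear2 and Ear6, or Bcl2a1a, Bcl2a1b and Bcl2a1d, or Csf2rb and Csf2rb2, may share reads, so their values are uncertain.

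Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2(normalized count + 1), IL-33 minus PBS, two-sided. Genes entered when their normalized count was at least 10 in at least 3 libraries. Benjamini-Hochberg adjustment covered all genes tested, and a gene was called at an adjusted p under 0.05. A fold change is on the log2(value + 1) scale, which understates the change of low genes. Means are given with the standard deviation (SD) over 3 libraries, and log2 fold changes with their standard error (SE). The replicate number was not used as a block.

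A set of 23 gene lists, for pathways and for markers of other cell types that the culture could hold, was fixed before the data were examined, together with the tests, the filter and most alternatives. Lists with at least 5 genes tested were compared with all other genes by limma's camera with a preset correlation between genes of 0.01, and 21 lists met that size. Their camera p-values were Benjamini-Hochberg adjusted over those lists. The list of mitochondrially encoded transcripts had 0 members in the table under the names searched and was not analysed here, and the lymphoid list had 4 genes tested. Camera was repeated with a correlation estimated for each list, and fry, which asks whether a list moves one way on balance, was also run.

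The rule for naming genes was also fixed in advance. It took the 12 largest and the 12 smallest log2 fold changes among called genes with a mean normalized count of at least 50 and no overlap between the groups, leaving out predicted gene models. It also took up to 5 called members per direction of each list, or, where fewer than 2 members were called, up to 2 with the smallest p. Il1rl1, Il1rap, Il5ra, Siglecf, Ccr3, Epx, Prg2, Il4, Il13, Il6 and Csf2 were always included. Genes outside this rule are named as chosen after their values were seen.

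The alternatives set in advance were other pseudocounts, no filter, a filter at 50, TMM scaling, scaling to equal totals, quantile normalization, no mean-variance trend, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 tests on the recovered reads, the replicate number as a block, each library left out in turn, and other list tests. Chosen after the data were seen were scaling to equal totals without Rn45s, removal of each library's trend with GC content and transcript length (splines with 5 degrees of freedom for each), a comparison of IL-33 replicate 1 alone with PBS, and the Rn45s share as a covariate. Counts of list members without a library cover the members that pass the filter in that fit, which can be fewer. With IL-33 replicate 1 alone, that library is assumed to vary like the PBS libraries. The IL-33 libraries varied more, at pairwise Pearson r of 0.922 to 0.969 on log2 values, against 0.984 to 0.987 among PBS libraries. Calls from that fit therefore overstate its certainty and do not cover the spread among IL-33 libraries.

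The limma step was tested on simulated counts for IL-33 against PBS with known changes, in a run of 10458 genes. Of 50 genes changed by log2 1, 4% were called, and of 49 changed by log2 −1, 0%. At log2 2 and log2 −2, with 50 genes each, 56% and 44% were called. Of 10259 unchanged genes, 3 were called. The adjusted threshold is stricter where few genes change, as here, than in the data, where 31.9% were called. These rates therefore do not give the recovery in the data. Figures were drawn with matplotlib 3.10.9.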

Results

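The transcriptome of cultured mouse eosinophils was profiled to ask how IL-33, an alarmin cytokine released by damaged tissue, changes gene expression within 3 hours. Eosinophils are granulocytes that carry cytotoxic proteins in their granules and depend on IL-5 for growth and survival. Cells matured from bone marrow in IL-5 received IL-33 at 2.5 ng/mL (3 libraries) or PBS (3 libraries), and ribosomal RNA-depleted total RNA was sequenced. The recovered reads numbered 9412814, 10785521 and 9362650 in IL-33 replicates 1, 2 and 3, and 8761710, 8981930 and 8218303 in PBS replicates 1, 2 and 3. Normalized counts per gene are given as mean ± SD with n = 3 in each group.

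The libraries differed in the share of reads that fell on Rn45s. Rn45s took 24.3%, 59.6% and 54.8% of the reads of IL-33 replicates 1, 2 and 3, and 24.8%, 23.3% and 13.7% of those of PBS replicates 1, 2 and 3. This left 7129435, 4355586 and 4229504 reads for other genes in the IL-33 libraries and 6592044, 6893099 and 7091546 in the PBS libraries. On log2 values, PBS libraries correlated at Pearson r of 0.984 to 0.987 across genes. IL-33 replicates 2 and 3 correlated at 0.969, replicates 1 and 2 at 0.952 and replicates 1 and 3 at 0.922. Genes are not independent replicates, and these r describe similarity only. The first principal component held 71.1% of the variance and separated the groups. The second held 16.8% and set IL-33 replicate 1, at 53.3, apart from the other libraries. No pair of libraries agreed within sampling noise, so none was treated as the same library listed again.

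**Figure D1:**
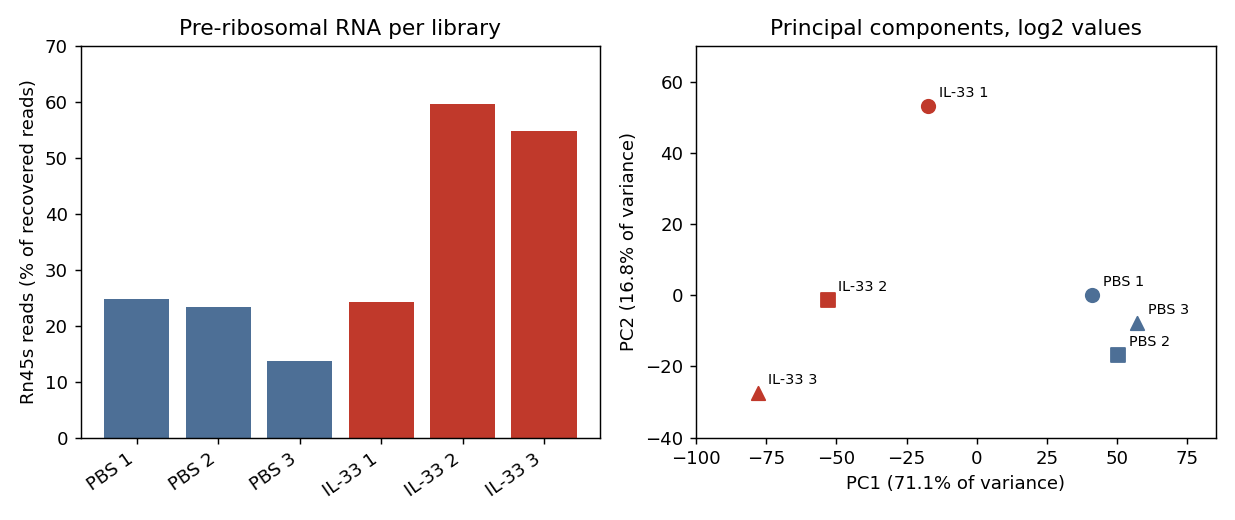
Left, bars show the share of recovered reads that fell on Rn45s in each library, in percent, from 13.7% in PBS replicate 3 to 59.6% in IL-33 replicate 2. Right, each point is a library placed by its first and second principal components of log2 values (71.1% and 16.8% of the variance). IL-33 libraries lie at negative first component values, and IL-33 replicate 1 lies apart on the second.

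IL-33 changed the expression of a large part of the genes detected. Of 10544 genes tested, 1837 were higher and 1522 were lower after IL-33 (limma, adjusted p under 0.05), 31.9% of those tested. At least 2-fold changes were called for 1146 higher and 1028 lower genes. In 5297 genes, 50.2% of those tested, the IL-33 and PBS values did not overlap, against 10% expected by chance. Tests on the recovered reads called 1909 higher and 1479 lower genes with edgeR and 2238 and 1624 with DESeq2. The counts depended on single libraries and on the scaling. They were 874 higher and 749 lower without IL-33 replicate 2, 2910 and 2950 without IL-33 replicate 1, 1108 and 595 without PBS replicate 1, 782 and 357 without PBS replicate 2, and 695 and 318 without PBS replicate 3. Over the 3359 genes called with all libraries, the median absolute log2 fold change was 0.90 in IL-33 replicate 1. The Rn45s share of that library lay within the PBS range. In the mean of replicates 2 and 3 the median was 1.32. Higher genes made up 54.7% of the calls as scaled by the authors, 4.50% after scaling to equal totals and 20.8% after scaling to equal totals without Rn45s. These scalings moved the median log2 fold change of all genes from −0.03 to −1.08 and −0.46 (log2). List medians and counts given below for these scalings include this shift of all genes. No gene was called in the opposite direction in any alternative.

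Genes of survival and innate signalling were among the largest increases. Tpbg, which encodes the membrane glycoprotein 5T4 (chromosome 9, 85842380 to 85847040), had 604 reads in the IL-33 libraries and 1 in the PBS libraries, a ratio of 1051 after scaling (95% exact interval 188 to 41575, counting error only). Of its exonic bases, 23.5% overlap exons of another gene. Pim2, a serine/threonine kinase that promotes survival (chromosome X, 7878262 to 7883432), went from 40.8 ± 7.14 to 4551 ± 1867 (log2 fold change 6.68, SE 0.33, adjusted p = 2.77e-05, limma). Traf1, an adaptor of tumor necrosis factor receptors (chromosome 2, 34941750 to 34961772), rose from 3.22 ± 2.37 to 327 ± 32.3 (6.47, SE 0.46, adjusted p = 1.18e-04, limma). Dusp2, a phosphatase of MAP kinases, had a log2 fold change of 5.60 (SE 0.46). Tlr9, the endosomal receptor for unmethylated DNA (chromosome 9, 106222598 to 106226883), rose from 53.3 ± 10.5 to 2051 ± 494 (5.23, SE 0.25, adjusted p = 2.36e-05, limma). Others among the largest 12 were Pou2f2 (4.90), Hpn (4.89), Peg10 (4.83), Itsn1 (4.81), Mfsd7a (4.77) and Efr3b (4.57), all log2 fold changes. The genes named in this paragraph were called without each library in turn, wherever they passed the filter on low values.

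Among the largest decreases were the IL-5 receptor and eosinophil ribonucleases. Il5ra, the alpha chain of the IL-5 receptor (chromosome 6, 106710357 to 106749037), fell from 275 ± 41.0 to 50.7 ± 23.9 (log2 fold change −2.53, SE 0.36, adjusted p = 0.0025, limma). Nxpe4 (−3.18), Atp8b5 (−2.80), Smc3, a cohesin subunit (−2.77), Mctp2 (−2.68) and Gria3 (−2.53) also fell, and were called without each library in turn wherever they passed the filter. Kif20b, a mitotic kinesin (−2.98), was not called without PBS replicate 2 (−2.83, adjusted p = 0.0504, limma). Rgs18 (−3.16), Ear1 (−3.07), Ear6 (−3.02), Arhgap15 (−2.79) and Rps4x, a ribosomal protein gene (−2.58), were not called in every fit. Without IL-33 replicate 2 their log2 fold changes were −3.22, −3.14, −2.89, −2.60 and −2.38, and the adjusted p were 0.0704, 0.0896, 0.124, 0.054 and 0.149 (limma). Each also lost its call without PBS replicate 3, at log2 fold changes of −3.10, −3.02, −2.96, −2.68 and −2.54. Without PBS replicates 1 or 2, Rgs18, Ear1, Ear6 and Rps4x were not called either, at log2 fold changes of −3.25, −3.13, −2.99 and −2.62 and of −3.12, −3.05, −3.11 and −2.59. Ear6 and Rps4x also lost their calls without IL-33 replicate 3 (−1.95 and −1.67). With IL-33 replicate 1 alone, the changes were smaller for Rgs18 (−1.28), Ear1 (−1.01), Ear6 (−0.62), Arhgap15 (−1.22) and Rps4x (−0.34). Ear1, Ear6 and Rps4x were not called by edgeR (−2.18, −1.89 and −1.64) or DESeq2 (−2.21, −1.96 and −1.64).

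**Figure D2:**
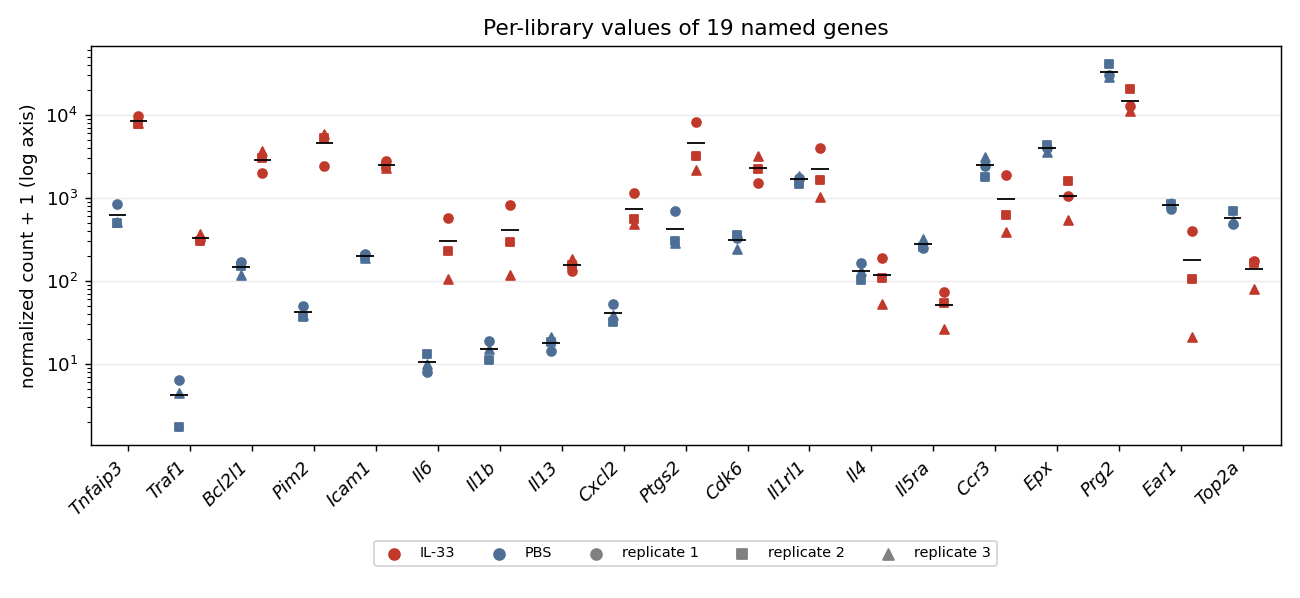
Normalized count + 1 of 19 named genes in each library, on a log axis, with PBS in blue, IL-33 in red, a marker for each replicate number and a black bar at the group mean. Traf1 lies between 306 and 364 in the IL-33 libraries before adding 1, against at most 5.44 in PBS, while the values of Il1rl1 overlap between groups.

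Genes of the NF-kB pathway and its feedback rose together. Of 27 list members tested, 20 were higher, 0 lower and 7 not called (21 higher when adjusted over the list alone), with a median log2 fold change of 2.44 (camera adjusted p = 5.9e-12, but adjusted p = 0.172 with an estimated correlation). Examples were Tnfaip3, which encodes the deubiquitinase A20 and limits NF-kB activity (chromosome 10, 19000910 to 19015657), from 622 ± 198 to 8517 ± 1067 (3.81, SE 0.23), Zc3h12a, an RNase that degrades cytokine mRNAs (3.79, SE 0.17), and Bcl3 (3.61, SE 0.21) and Nfkbiz (3.41, SE 0.29), which are nuclear partners of NF-kB. The list median was 2.23, 2.37 and 2.53 in IL-33 replicates 1, 2 and 3. It remained above 0 under every scaling, although scaling to equal totals called 14 members higher and 6 lower.

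The receptor for IL-33 itself did not pass the test with all libraries. Il1rl1, which encodes ST2 (chromosome 1, 40429570 to 40465415), averaged 1689 ± 174 in PBS and 2208 ± 1543 after IL-33 (log2 fold change 0.16, SE 0.42, adjusted p = 0.788, limma), with 3951, 1658 and 1015 in IL-33 replicates 1, 2 and 3. With IL-33 replicate 1 alone its log2 fold change was 1.23, in a comparison without any spread among IL-33 libraries. Il1rap, its co-receptor, had a log2 fold change of 0.28 (SE 0.21, adjusted p = 0.326, limma). Of 23 members of the IL-33 receptor and MyD88 signalling list, 7 were higher, 3 lower and 13 not called (7 and 3 adjusted over the list alone), and the list did not pass camera (median 0.19, adjusted p = 0.144). Scaled to equal totals, 3 were higher and 6 lower (median −0.85), and without Rn45s 4 and 5 (median −0.24). Those that rose included Irak3, a negative regulator of the pathway, from 189 ± 43.5 to 2137 ± 283 (3.51, SE 0.22), the p38 target kinase Mapkapk2 (2.98, SE 0.25), Irak2 (2.59, SE 0.20) and the adaptor Myd88 (1.65, SE 0.32). The counts were 4 higher and 0 lower without IL-33 replicate 2, PBS replicate 2 or PBS replicate 3, 7 and 0 without PBS replicate 1, 8 and 5 without IL-33 replicate 1, and 11 and 3 with IL-33 replicate 1 alone.

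Cytokine and chemokine genes were among those that rose. Of 20 cytokine and growth factor genes tested, 14 were higher, 2 lower and 4 not called, with the same counts adjusted over the list alone (median 1.40, camera adjusted p = 6.0e-05, but adjusted p = 0.172 with an estimated correlation). Il6 (chromosome 5, 30013114 to 30019981) went from 9.48 ± 2.71 to 299 ± 240.2 (4.54, SE 0.55), Il1b from 14.01 ± 3.84 to 411 ± 365 (4.39, SE 0.61) and Il13, a type 2 cytokine (chromosome 11, 53631324 to 53634702), from 16.98 ± 3.56 to 157 ± 25.5 (3.14, SE 0.26, adjusted p = 2.46e-04, limma). Flt3l was lower (−1.59, SE 0.26), and 22.1% of its exonic bases overlap exons of another gene. Il4, the neighbour of Il13, was not called, at 132 ± 31.1 and 116 ± 67.6 (−0.34, SE 0.43). Csf2 lay below the filter, at 8.99, 1.54 and 1.69 in the IL-33 libraries and 0.777, 0 and 2.10 in the PBS libraries, and was not tested. Without PBS replicate 2 the cytokine list had 9 higher and 1 lower, without PBS replicate 1 13 and 1, without PBS replicate 3 10 and 1, without IL-33 replicate 3 14 and 1, and without IL-33 replicate 1 15 and 4. After scaling to equal totals 4 were higher and 3 lower.

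Of 11 chemokine genes tested, 7 were higher and 0 lower, also when adjusted over the list alone (median 1.45, camera adjusted p = 0.00552, but adjusted p = 0.371 with an estimated correlation). Cxcl2, a neutrophil attractant, rose from 40.1 ± 10.2 to 726 ± 364 (4.06, SE 0.35), its neighbour Cxcl3 from 44.6 ± 12.5 to 395 ± 163 (3.08, SE 0.32), and Cxcl10 from 2.66 ± 1.05 to 40.0 ± 13.9 (3.47, SE 0.43). Without any one IL-33 library 9 chemokine genes were tested, since Cxcl10 and Cxcl16 lay below the filter. The counts were then 3 higher and 0 lower without IL-33 replicate 2 (median 1.30), 4 and 0 without IL-33 replicate 3 (median 1.04), and 5 and 2 without IL-33 replicate 1, when the list was also no longer called (median 1.17, camera adjusted p = 0.315). With equal totals 4 were higher and 2 lower (median 0.43).

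Immediate early genes and feedback regulators of MAP kinase and JAK-STAT signalling were higher as groups. Of 31 immediate early genes, 20 were higher and 0 lower, also when adjusted over the list alone (median 1.16, camera adjusted p = 1.61e-06, but adjusted p = 0.319 with an estimated correlation). Maff (3.05, SE 0.25), Ier5 (3.01, SE 0.42), Ier3 (2.74, SE 0.30) and Egr2 (2.20, SE 0.38) were examples. Of 30 feedback genes, 20 were higher and 1 lower, also when adjusted over the list alone (median 1.34, camera adjusted p = 1.05e-08, but adjusted p = 0.256 with an estimated correlation). Besides Pim2 and Dusp2, the kinase genes Pim1 (3.56, SE 0.19) and Pim3 (3.47, SE 0.31) and the stress gene Gadd45b (3.48, SE 0.25) rose. The lower gene, Rgs2 (−1.24), was not called without PBS replicate 3 (−1.22, adjusted p = 0.0543, limma). The immediate early list had 13 higher without IL-33 replicate 2 or PBS replicate 2 and 11 without PBS replicate 3. With equal totals the median of the immediate early list was 0.07, with 4 higher and 4 lower, and that of the feedback list 0.30, with 12 higher and 3 lower.

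Bcl2l1, which encodes the anti-apoptotic protein Bcl-xL (chromosome 2, 152780668 to 152831728), went from 145 ± 26.1 to 2884 ± 846 (log2 fold change 4.27, SE 0.26, adjusted p = 6.19e-05, limma). Of 32 apoptosis and survival genes, 15 were higher, 1 lower and 16 not called (16 and 1 adjusted over the list alone), with a median of 0.68, which was −0.36 after scaling to equal totals, with 4 higher and 9 lower (camera adjusted p = 2.17e-04, but adjusted p = 0.172 with an estimated correlation). The members that rose act in different ways, among them Nlrp3, an inflammasome sensor (2.48, SE 0.26), and Cdkn1a, which encodes the cell cycle inhibitor p21 (2.36, SE 0.21). Bcl2a1d rose as well (3.19, SE 0.75), although it may share reads with Bcl2a1a and Bcl2a1b, and it was not called without PBS replicate 2 (2.64, adjusted p = 0.0645, limma) or PBS replicate 3 (3.36, adjusted p = 0.0572, limma). The list had 9 higher without PBS replicate 2 and 7 without PBS replicate 3, and the lower gene, Apaf1 (−0.68), was not called in either case (−0.59 and −0.69) or without IL-33 replicate 2 (−0.70).

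Eosinophil genes moved in both directions. Granule protein genes fell: Epx, which encodes eosinophil peroxidase (chromosome 11, 87864000 to 87875536), went from 3999 ± 431 to 1061 ± 528 (−2.04, SE 0.35, adjusted p = 0.00507, limma), and Prg2, which encodes major basic protein (chromosome 2, 84980461 to 84983632), from 33228 ± 6825 to 14861 ± 5241 (−1.20, SE 0.26, adjusted p = 0.0128, limma). Prg2 was not called without PBS replicate 2 (−1.04, adjusted p = 0.0632, limma). Higher members included the transcription factor genes Cebpa (2.79, SE 0.30) and Gata1 (1.53, SE 0.26) and the pseudokinase gene Trib1 (1.45, SE 0.19). Of 25 list members tested, 7 were higher, 10 lower and 8 not called (9 and 11 adjusted over the list alone), and the list did not pass camera (median −0.35, adjusted p = 0.489). Ccr3, the eotaxin receptor, had a log2 fold change of −1.65 (SE 0.52, adjusted p = 0.042, limma). Ccr3 was not called without IL-33 replicate 2 (−1.50) or 3 (−1.15), or PBS replicate 1 (−1.64), 2 (−1.85) or 3 (−1.45). It was not called by edgeR either (−1.36), and its log2 fold change was −0.35 with IL-33 replicate 1 alone. Siglec5, the table's name for Siglecf, was not called (−0.54, SE 0.31), but was lower without IL-33 replicate 1 (−0.91) and after scaling to equal totals with (−1.58) or without Rn45s (−0.96). The list had 3 higher and 7 lower without IL-33 replicate 2, 3 and 8 without IL-33 replicate 3, 3 and 6 without PBS replicate 1 or 3, 3 and 5 without PBS replicate 2, and 3 and 10 with IL-33 replicate 1 alone. When scaled to equal totals, it had 1 higher and 16 lower.

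Adhesion molecules and chemoattractant receptors also went both ways. Icam1, the adhesion ligand of beta-2 integrins (chromosome 9, 21015985 to 21028817), rose from 197 ± 10.7 to 2500.1 ± 254 (3.66, SE 0.16, adjusted p = 1.96e-05, limma), and the complement receptor gene C5ar1 (1.88, SE 0.29) and the nucleotide receptor gene P2ry2 (1.23, SE 0.18) were higher. Selp, which encodes P-selectin, fell from 81.3 ± 10.7 to 16.9 ± 4.12 (−2.22, SE 0.27). Of 33 members, 8 were higher, 10 lower and 15 not called (8 and 11 adjusted over the list alone), and the list did not pass camera (median −0.08, adjusted p = 0.683). Scaling to equal totals called 1 higher and 17 lower (median −1.12), and without Rn45s 5 and 14. The counts were 5 and 6 without IL-33 replicate 2, 5 and 5 without PBS replicate 1, 3 and 5 without PBS replicate 2 and 3 and 2 without PBS replicate 3. Of 18 lipid mediator genes, 5 were higher and 4 lower, also when adjusted over the list alone (median 0.31, camera adjusted p = 0.599). Ptgs2, the inducible cyclooxygenase gene, rose from 427 ± 235 to 4539.7 ± 3213 (3.31, SE 0.51), and Lta4h, the leukotriene A4 hydrolase gene, fell from 786 ± 37.3 to 337 ± 81.0 (−1.24, SE 0.20). The lipid list had 3 higher and 2 lower without IL-33 replicate 2, 3 and 3 without PBS replicate 1, and 2 and 1 without PBS replicate 2 or 3. Its median became −0.71 after scaling to equal totals, with 1 higher and 6 lower.

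Antigen presentation, interferon and tissue remodelling lists did not pass camera. Of 27 antigen presentation and costimulation genes, 7 were higher and 3 lower, also when adjusted over the list alone (median 0.41, adjusted p = 0.106). Tnfrsf9, which encodes the costimulatory receptor 4-1BB, rose from 3.43 ± 0.490 to 87.5 ± 15.6 (4.31, SE 0.31), and the class I gene H2-K1 from 3025 ± 242 to 6564 ± 1175 (1.11, SE 0.18). Without PBS replicate 3 the counts were 3 and 0, without PBS replicate 2 or IL-33 replicate 2 3 and 1, without PBS replicate 1 6 and 1, without IL-33 replicate 3 8 and 2, and without IL-33 replicate 1 9 and 5. Of 21 interferon-stimulated genes, 5 were higher and 4 lower, also when adjusted over the list alone (median −0.41, adjusted p = 0.291). The list median lay between −0.59 and −0.39 without any one library, but fewer members were called in most of these fits: 0 were higher and 2 lower without IL-33 replicate 2 or PBS replicate 1, 0 and 1 without PBS replicate 2, 0 and 0 without PBS replicate 3, 2 and 4 without IL-33 replicate 3, 4 and 8 without IL-33 replicate 1, and 1 and 4 with IL-33 replicate 1 alone. With equal totals 0 were higher and 13 lower (median −1.42), and without Rn45s 1 and 11 (median −0.82). Of 18 alternative activation and tissue remodelling genes, 6 were higher and 1 lower, also when adjusted over the list alone (median 0.28, adjusted p = 0.231). Tgm2, the transglutaminase 2 gene, rose from 222 ± 70.3 to 1602 ± 466 (2.86, SE 0.29), with 21.8% of its exonic bases overlapping exons of another gene. Il4ra, the shared receptor chain for IL-4 and IL-13, rose from 423 ± 45.1 to 1383 ± 230.4 (1.70, SE 0.18). The lower gene, Chi3l3 (−1.53), was not called without IL-33 replicate 2 (−1.23) or 3 (−1.22), or by edgeR (−1.23). It was not called without PBS replicate 1 (−1.39), 2 (−1.71) or 3 (−1.50) either. The list had 3 higher without IL-33 replicate 2 or PBS replicate 1 and 2 without PBS replicate 2 or 3. The medians of the antigen presentation and remodelling lists were −0.61 (2 higher and 6 lower) and −0.79 (1 and 4) after scaling to equal totals.

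Glycolysis and hypoxia genes rose. Of 29 tested, 17 were higher, 1 lower and 11 not called (18 and 2 adjusted over the list alone), with a median of 0.82, which was −0.20 after scaling to equal totals, with 1 higher and 7 lower (camera adjusted p = 1.63e-05, but adjusted p = 0.333 with an estimated correlation). Slc16a3, the lactate exporter gene, rose from 1752 ± 147 to 7493 ± 2744 (2.03, SE 0.26), Ero1l, an oxidase of the endoplasmic reticulum, from 5354 ± 1729 to 21009.7 ± 3225 (2.01, SE 0.24), the oxygen-sensing hydroxylase gene Egln3 from 284 ± 53.5 to 1157 ± 375 (1.99, SE 0.25) and Pfkl, a phosphofructokinase gene, from 636 ± 89.7 to 2323 ± 263 (1.87, SE 0.17). The list median was 1.27 in IL-33 replicate 1 and 0.69 and 0.61 in replicates 2 and 3. The lower gene, Pfkfb4 (−0.79), was not called without IL-33 replicate 2 (−0.76) or 3 (−0.71), without PBS replicate 1 (−0.89), 2 (−0.68) or 3 (−0.81), or with IL-33 replicate 1 alone (−0.57). Without IL-33 replicate 1 the list had 19 higher and 5 lower.

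Sterol and stress genes were mixed. Of 32 cholesterol and fatty acid synthesis genes, 10 were higher and 4 lower (11 and 5 adjusted over the list alone, median 0.10, camera adjusted p = 0.35), with the cholesterol exporter gene Abca1 at 2.56 (SE 0.35) and Mylip, which targets the LDL receptor for degradation, at 1.75 (SE 0.18). The counts were 5 and 4 without IL-33 replicate 2, 6 and 4 without PBS replicate 1, 4 and 1 without PBS replicate 2 or 3, and 11 and 7 without IL-33 replicate 1. Of 31 unfolded protein and heat shock genes, 13 were higher and 3 lower, also when adjusted over the list alone (median 0.42, camera adjusted p = 0.0681). Calr, which encodes the chaperone calreticulin, fell from 2350.4 ± 639 to 988 ± 188 (−1.23, SE 0.24). The list passed camera without IL-33 replicate 2 (adjusted p = 0.0229), IL-33 replicate 3 (0.0354) or PBS replicate 1 (0.0217). It also passed with the replicate number as a block, as given below. The heat shock gene Hspa1b (2.07, SE 0.59), at 1474, 378 and 651 in IL-33 replicates 1, 2 and 3 and 383, 98.2 and 128 in PBS replicates 1, 2 and 3, was not called without PBS replicate 2 (1.68), PBS replicate 3 (1.87) or IL-33 replicate 3 (2.14), or after the GC and length correction (1.67). This list had 2 higher and 1 lower without PBS replicate 2 or 3, 7 and 3 without IL-33 replicate 2, and 13 and 7 without IL-33 replicate 1. After scaling to equal totals the medians of the sterol and stress lists were −0.94 (1 higher and 13 lower) and −0.62 (0 and 9).

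Cell cycle genes fell. Of 37 tested, 17 were lower, 2 higher and 18 not called (22 and 2 adjusted over the list alone), with a median of −1.09 (camera adjusted p = 1.73e-06, but adjusted p = 0.333 with an estimated correlation). Top2a, the DNA topoisomerase of dividing cells (chromosome 11, 98992943 to 99024189), went from 568 ± 109 to 137 ± 51.5 (−2.11, SE 0.32, adjusted p = 0.00295, limma) and the spindle checkpoint gene Bub1 from 34.6 ± 5.08 to 3.14 ± 1.49 (−3.17, SE 0.41). The higher genes were Cdk6 (chromosome 5, 3341485 to 3531008), from 310.0 ± 59.0 to 2302 ± 819 (2.85, SE 0.28), and Ccnd2 (1.56, SE 0.19), which encode a kinase and a cyclin of the first gap phase. The list median was below 0 under every scaling, with 1 higher and 34 lower at equal totals, and it was −1.20, −0.75 and −1.18 in IL-33 replicates 1, 2 and 3. The list had 10 lower without PBS replicate 1, 7 without PBS replicate 2 or 3, and 29 with IL-33 replicate 1 alone.

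**Figure D3:**
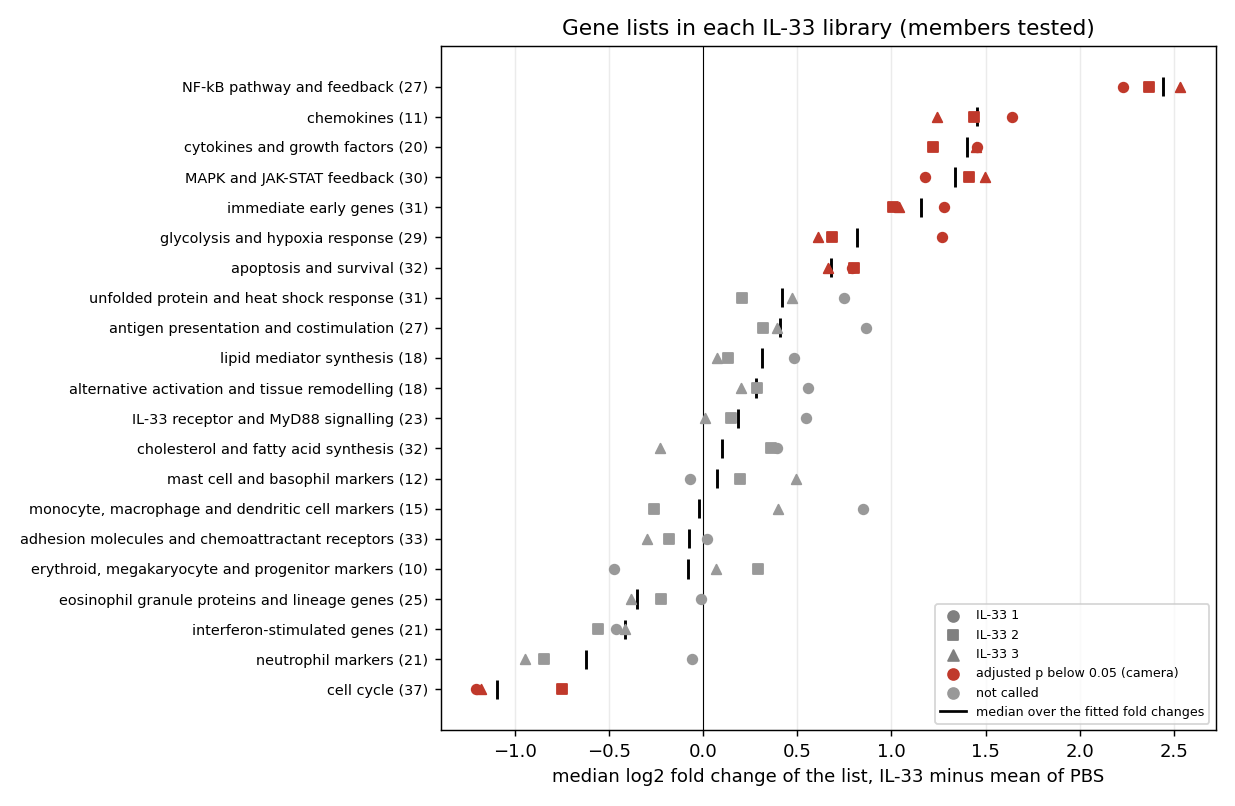
Median log2 fold change over PBS of each of the 21 gene lists tested, with one marker per IL-33 library and a black bar for the median of the fitted fold changes. Lists in red passed camera with the preset correlation, and the number of members tested stands in parentheses. NF-kB medians lie between 2.23 and 2.53, while those of the neutrophil list lie between −0.95 and −0.06. The positive medians of the apoptosis list and of the glycolysis list became −0.36 and −0.20 after scaling to equal totals. That scaling moved the median of all genes tested to −1.08.

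No list of markers for other cell types passed camera in the comparison set in advance, although 2 passed in alternatives given below, and single markers went both ways. Neutrophil markers had 2 higher, 7 lower and 12 not called of 21 (2 and 8 adjusted over the list alone, median −0.62, camera adjusted p = 0.0538), with medians of −0.06, −0.85 and −0.95 in IL-33 replicates 1, 2 and 3. Padi4, a histone-modifying enzyme gene, fell (−1.34, SE 0.17) and the receptor gene Trem1 rose (1.99, SE 0.28). The lower markers numbered 12 without IL-33 replicate 1, 3 without IL-33 replicate 2 and 4 without IL-33 replicate 3. They numbered 2 without PBS replicate 1 and 1 without PBS replicate 2 or 3. The list passed camera without IL-33 replicate 1 (median −1.02, adjusted p = 0.0214) and with no mean-variance trend (adjusted p = 0.043). It also passed camera on ranks (adjusted p = 0.0493) and with the replicate number as a block, as given below. Of 12 mast cell and basophil markers, 3 were higher and 2 lower, also when adjusted over the list alone (median 0.08, mean −0.04, camera direction up, adjusted p = 0.59), with the mast cell protease gene Cpa3 at −2.81 (SE 0.40) and the steroid enzyme gene Cyp11a1 at 0.81 (SE 0.15), the latter −0.24 after scaling to equal totals. The lower markers, Cpa3 and Ms4a2, lay below the filter without any one PBS library, and without IL-33 replicate 2 or 3 Cpa3 was called and Ms4a2 was not. Of 15 monocyte, macrophage and dendritic cell markers, 5 were higher and 1 lower, also when adjusted over the list alone (median −0.02, mean 0.48, camera direction up, adjusted p = 0.231). That list passed camera after scaling to equal totals (median −1.04, adjusted p = 0.017), where it was up relative to other genes. The median of all genes was then −1.08. It also passed camera with the Rn45s share as a covariate (0.69, adjusted p = 0.0262). Cd14, a co-receptor for endotoxin, rose from 73.1 ± 29.8 to 904 ± 105 (3.68, SE 0.28), and Batf3 (2.17, SE 0.30), Emr1, which encodes F4/80 and is also found on mouse eosinophils (1.48, SE 0.19), and Csf1r (1.40, SE 0.16) were higher. The lower marker of that list, Ccr2 (−1.91), was not called without IL-33 replicate 2 (−1.53) or PBS replicate 1 (−1.89) or 3 (−1.69). Of 10 erythroid, megakaryocyte and progenitor markers, 3 were higher and 2 lower (3 and 3 adjusted over the list alone, median −0.08, camera adjusted p = 0.967), with Procr at 3.05 (SE 0.34) and Erg at −3.30 (SE 0.74). Procr lay below the filter without any one IL-33 library, and Erg without any one PBS library. Of 7 members tested, 0 were higher and 2 lower without IL-33 replicate 2 and 1 and 3 without IL-33 replicate 3, and the list had 3 and 1 without PBS replicate 1, 1 and 1 without PBS replicate 2 or 3, 3 and 4 without IL-33 replicate 1, and 1 and 3 with IL-33 replicate 1 alone. Of the 4 lymphoid markers tested, 0 were called by limma at the adjusted threshold, 1 had an unadjusted p under 0.05, and 0 were called by edgeR or DESeq2. Without IL-33 replicate 2 or with IL-33 replicate 1 alone, 1 was called lower, and 3 were lower with equal totals and 2 with equal totals without Rn45s. Those with the smallest p were Il17rb (−0.89, SE 0.37) and Cd79a (−0.52, SE 0.24). For the neutrophil, mast cell, monocyte and erythroid lists, equal totals gave 0 higher and 14 lower, 0 and 6, 2 and 6, and 1 and 6.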

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

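Scaling to equal totals without Rn45s, the GC and length correction, IL-33 replicate 1 alone and the Rn45s share as a covariate were chosen after the data were seen, and no gene was called in the opposite direction under any alternative. The cause of the changes below was not tested, except that fewer libraries or genes, as well as a covariate tied to the groups, lower the power of a fit. Pseudocounts, no filter, TMM scaling, quantile normalization, no mean-variance trend, edgeR, DESeq2, the replicate block, the GC and length correction and IL-33 replicate 1 alone kept all 4 counts of genes within 1.5 times those reported. Leaving out one library gave 695 to 2910 higher and 318 to 2950 lower genes, and 630 to 1513 higher and 296 to 1740 lower at 2-fold, with the lowest counts without PBS replicate 3 and the highest without IL-33 replicate 1. A filter at 50 gave 651 genes lower at 2-fold, since it removes low genes. Equal totals gave 255 higher and 5414 lower (213 and 5016 at 2-fold), and equal totals without Rn45s 942 and 3595 (574 and 2392). With the Rn45s share as a covariate, highest in IL-33 replicates 2 and 3, 606 were higher and 373 lower (555 and 342 at 2-fold), 13 lists were called, and 75 of 170 named genes lost their call. The GC and length correction gave 1927 higher and 1757 lower, with 1590 and 1366 of them shared with the calls reported. The labels do not say whether the replicate numbers pair the libraries. Deviations of same-numbered libraries correlated at 0.05, 0.24 and −0.16 for replicates 1, 2 and 3, and not every library correlated best with its own number. This check runs over all genes, where other differences between the IL-33 libraries enter, so it cannot exclude pairing. With the replicate block 1620 genes were higher and 1298 lower, and the stress list (median 0.42, adjusted p = 0.00628) and the neutrophil list (median −0.62, adjusted p = 0.0328) passed camera.

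With a correlation estimated for each list, 0 lists were called, at unchanged medians of 2.44 (NF-kB), 1.40 (cytokines), 1.45 (chemokines), 1.16 (immediate early), 1.34 (MAPK and JAK-STAT feedback), 0.68 (apoptosis), 0.82 (glycolysis) and −1.09 (cell cycle), and fry called 9, the IL-33 receptor list (0.19) among them. The list medians below belong to calls gained, unless said otherwise. Without a filter these were the IL-33 receptor (0.19), antigen presentation (0.41) and stress (0.42) lists, and with camera on ranks or no mean-variance trend the neutrophil list (−0.62). Chemokines lost their call at a filter of 50 (1.40). With equal totals the antigen presentation (−0.61), stress (−0.62) and monocyte (−1.04) lists were called, up relative to other genes, and without Rn45s antigen presentation (−0.0091) and stress (−0.0038). The GC and length correction called the IL-33 receptor (0.36) and stress (0.52) lists. IL-33 replicate 1 alone called IL-33 receptor (0.55), antigen presentation (0.86), remodelling (0.56) and stress (0.75), and the Rn45s covariate the same lists (0.51, 0.88, 0.53 and 0.56) and monocyte markers (0.69). Leaving out one library gave medians of 0.039 to 0.31 for the IL-33 receptor list, 0.32 to 0.61 for antigen presentation, 0.34 to 0.49 for stress, 1.04 to 1.83 for chemokines and −1.02 to −0.43 for neutrophil markers. The IL-33 receptor list passed camera without IL-33 replicate 3 (adjusted p = 0.0354), antigen presentation without PBS replicate 1 (0.0259), stress without IL-33 replicate 2 (0.0229), IL-33 replicate 3 (0.0354) or PBS replicate 1 (0.0217) and neutrophil markers without IL-33 replicate 1 (0.0214), while chemokines did not without IL-33 replicate 1 (0.315). Equal totals reversed 12 named genes, none of them called there: Traf6 (−0.30), Csf2ra (−0.0010), Itgb2 (−0.18), Lpcat2 (−0.052), Ptges2 (−0.28), Irf9 (−0.21), Ifi35 (−0.34), Cyp51 (−0.13), Mmp25 (−0.18), Lgals3 (−0.36), Cyp11a1 (−0.24) and Tfrc (−0.10). Pseudocounts and TMM scaling changed no named call. Depth limits low genes: 470 of the 1522 lower and 220 of the 1837 higher calls had a mean under 50.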

Other observations

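The gene groups of the next paragraphs were chosen after the values were seen, as were the test of NF-kB medians between IL-33 replicates and that of other cell type markers called lower. Of 19 targets of NRF2, the transcription factor of the antioxidant response, 13 were higher, 0 lower and 6 not called (no test of the group was run), with a median log2 fold change of 0.82 that became −0.22 after scaling to equal totals (1 higher and 3 lower) and 0.26 with quantile normalization (5 and 2). Sqstm1, which encodes the autophagy receptor p62, rose from 9444 ± 2178 to 66320 ± 4197 (2.83, SE 0.20), the thioredoxin reductase gene Txnrd1 from 6639 ± 1525 to 25311 ± 4482 (1.94, SE 0.21), Gclc, the catalytic subunit gene for glutathione synthesis, from 2487 ± 709 to 8811 ± 523 (1.86, SE 0.21) and Mafg by a log2 fold change of 1.68 (SE 0.21). Nqo1, a standard NRF2 target, was not called (−0.69, SE 0.42), but was lower without IL-33 replicate 1 (−1.25). The higher genes numbered 9 without IL-33 replicate 2 or PBS replicate 1, 7 without PBS replicate 2 and 4 without PBS replicate 3, and 16 with IL-33 replicate 1 alone.

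Of the toll-like receptor genes, 4 were tested and 2 rose, Tlr9 and Tlr2. Tlr2 went from 17.1 ± 7.56 to 114.6 ± 30.2 (2.72, SE 0.35, adjusted p = 0.0016, limma), while Tlr4 (−0.71, SE 0.39) and Tlr13 (−0.02, SE 0.35) were not called, except that Tlr4 was lower without IL-33 replicate 1 (−1.13). With equal totals 2 of 5 tested were higher and 1 lower. Of 74 cytoplasmic ribosomal protein genes, 14 were lower, 3 higher and 57 not called, with medians of 0.05, −0.81 and −1.16 in IL-33 replicates 1, 2 and 3. Scaled to equal totals 0 were higher and 56 lower, without Rn45s 1 and 43, and with quantile normalization 2 and 27. On the recovered reads, edgeR called 4 higher and 6 lower, and DESeq2 5 and 13. The lower ones numbered 53 without IL-33 replicate 1, 0 without IL-33 replicate 2, PBS replicate 2 or PBS replicate 3, 1 without PBS replicate 1 and 3 without IL-33 replicate 3. Rn45s itself was higher (2.15, SE 0.60, adjusted p = 0.0286, limma), although its share in IL-33 replicate 1 lay within the PBS range. Whether precursor or mature ribosomal RNA gave these reads was not tested. Of 30 small nucleolar RNA genes, 11 were higher and 0 lower (median 0.96, and −0.05 with 1 higher and 1 lower after scaling to equal totals), and after the GC and length correction 7 were higher and 1 lower (median 0.52). The higher ones numbered 1 without IL-33 replicate 2 or PBS replicate 2, 2 without PBS replicate 3, 5 without PBS replicate 1, 6 without IL-33 replicate 3 and 15 without IL-33 replicate 1.

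IL-33 replicates 2 and 3 lay apart from IL-33 replicate 1 in Rn45s share, ribosomal protein genes and the second principal component. Among genes with a mean of at least 500, the difference had an SD of 0.71, against 0.061 expected from counting (11.7 times). PBS libraries also exceeded counting noise (3.39 to 4.30 times). Counting error of independently drawn reads is too small to give a spread of this size in these genes. Since the PBS libraries exceeded it as well, the test does not show what set replicate 1 apart. Lower genes were not covered by this test. The NF-kB list argued against a smaller response to IL-33 in replicate 1, since its median there differed by −0.14 from the lower of the others. Over all calls, however, the median absolute log2 fold change was 0.90 in replicate 1 and 1.32 in the mean of replicates 2 and 3, so a smaller response of other genes stays open. GC content and transcript length explained 21.2% of the variance of the difference, between the bounds of 5% and 25% set for the test, so their part cannot be told apart from other differences between these libraries.

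The genes lower after IL-33, and likewise those higher, could in part reflect the same GC trend. The median log2 fold change was −0.35 in genes with a GC content up to 45.03% and 0.31 in those above 54.6%. The trend lay in IL-33 replicates 2 (−0.35 and 0.35) and 3 (−0.64 and 0.59), and not in replicate 1 (0.01 and 0.03). With that trend and that of length removed, 90.5% of the lower calls with values were still called lower. This argues against the trend as the whole cause of the lower calls. Of the higher calls with values, for which no bound was set, 87.5% were still called higher. Effects of the library steps that do not follow GC content or length stay open.

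Granule protein genes (Epx, Prg2, Prg3, Ear1, Ear2 and Ear6) had a median log2 fold change of −2.53, with −1.36, −2.12 and −3.43 in IL-33 replicates 1, 2 and 3. After the GC and length correction the median was −2.55, which argues against that bias as the cause. A lower share of eosinophils would raise markers of other cell types alike only if those cells gained share alike and IL-33 left the markers themselves unchanged. Neither condition was tested. Of 61 such markers, 13 were called higher and 12 lower. Without PBS replicates 1, 2 and 3, where fewer libraries and markers were tested, 3, 3 and 2 were called lower. In those fits the neutrophil median was −0.66, −0.72 and −0.73, against −0.62 with all libraries. The mast cell and basophil median was 0.41, 0.48 and 0.49, against 0.08. The test of these markers was revised more than once after results were seen. Its first version decided nothing either (1 of 5 list medians above 0, no list below 0 past camera). A lower share of eosinophils therefore stays open, as do a fall of these transcripts in response to IL-33 and reads shared among the Ear genes, which were not tested.

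Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 1837 higher and 1522 lower genes, and 1146 and 1028 at 2-fold, while the highest count of the other splits was 0 for each, so 1 split reached each real count. For the gene list tests, 7 of the 10 splits, the real one included, called as many lists as the real 8, and the highest of the others called 14. The other splits that did so were the 6 that put IL-33 replicate 1 with 1 other IL-33 library and 1 PBS library, which points to a structure of the samples. The number of lists called by camera with the preset correlation therefore did not set the real grouping apart. Each other split, however, has unequal numbers of IL-33 libraries on its sides, so part of any IL-33 effect stays in it. These splits therefore cannot tell lists called by chance from lists called through the treatment.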
